A study of Mus musculus with 12 samples.

How the data were processed

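CD4+ T cells were taken by magnetic negative selection from spleens or lymph nodes of male C57BL/6 mice, WT or Adcy10-/-, aged 8 to 10 weeks. Per the labels they were cultured for 18 hours on plate-bound anti-CD3 (10 µg/mL) with anti-CD28 (2 µg/mL), IL-1β (20 ng/mL), IL-6 (25 ng/mL), IL-23 (20 ng/mL), and antibodies to interferon-γ and IL-4 (1 µg/mL each). The description does not split these additions between baseline medium and baseline medium with polarizing cytokines. The 12 libraries form 4 groups of 3: WT and Adcy10-/- in each medium. Adcy10-/- is written KO in the names of libraries.

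The deposited files hold FPKM per gene, made by the authors. Per the submitters' processing notes, reads were aligned to mm9 with STAR 2.4.0f1 and handled with SAMtools 0.1.19, and expression was summarized with Cufflinks and HTSeq, for which no version is given. FPKM carries neither read counts nor depth, so the precision that depth gives each library is unknown and only the spread between libraries measures error. Each file held 24488 entries for 23991 gene IDs. Entries of the 258 IDs listed several times (755 entries) were summed. All 12 libraries were used.

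Values were transformed as log2(FPKM + 1), with no further scaling. The added 1 pulls fold changes of genes near or below 1 FPKM toward 0, so their changes are understated. Genes with at least 1 FPKM in at least 3 libraries were tested (10126 of the 16728 above 0 in any library). Models were fitted with limma 3.58.1 in R 4.3.3, with the package data.table (1.17.8), as 4 group means with empirical Bayes moderation and a trend of variance with expression. The 6 contrasts were cytokines minus baseline in each genotype, Adcy10-/- minus WT in each medium and averaged over media, and the interaction (the cytokine effect in Adcy10-/- minus that in WT). Adjusted p-values are from limma with the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Errors are moderated SE and intervals are 95%. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

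Fixed gene lists were written from general knowledge before the values were seen. They covered Th17 cytokines, Th17 factors and receptors, Th1, Th2, regulatory T cell, JAK-STAT3, NF-kB and IL-1, cAMP-CREB, cAMP pathway, T cell activation, naive and quiescence, interferon-stimulated, cell cycle, glycolysis, hypoxia, respiratory chain, cholesterol, integrated stress, unfolded protein, ribosomal, apoptosis and chemokine receptor genes. Further lists held markers of B, CD8 T, NK, macrophage, dendritic, neutrophil, red and gamma delta T cells, CD4 T cell identity genes, and the neighbors of Adcy10. Lists were tested with camera in limma, with a preset correlation between genes of 0.01 and, as an alternative, with a correlation estimated from the residuals, and adjusted over the lists of a contrast. Members were also counted with p-values adjusted over the list alone.

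The genes named were set by rule before the values were seen. They were Adcy10, a fixed panel, the 10 largest changes each way among genes that passed, did not overlap between groups and reached a mean of 5 FPKM (without predicted genes, small RNAs and receptor segments), up to 4 members of each list with the largest passing change (or the smallest p), and the 5 smallest p-values where fewer than 5 genes passed. Genes named outside this rule are said to be so, and some genes within it are not reported here.

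Whether libraries with the same replicate number belong together was checked on residuals before the blocked fits were compared. Libraries of the same number and genotype correlated at 0.294 to 0.536 (median 0.449, 6 pairs), those of the same number and the other genotype at 0.074 to 0.523 (median 0.322, 12 pairs), and the best partner shared the number for 12 of 12 libraries. The block is therefore reported beside both cytokine effects and the genotype effect with cytokines. Its gene counts are also given beside the baseline and averaged genotype effects. Its other results for the baseline, averaged and interaction contrasts were left to the closing section, since 1 baseline pair lay at 0.074. That pair joined the 2 genotypes, so the block within genotype, which pairs only libraries of the same number and genotype, is also given beside both cytokine effects.

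The pipeline was tested on simulated data for 10126 genes, of which 200 were changed, 50 each at 1.5-fold, 2-fold, 4-fold and 8-fold. At 1.5-fold and 2-fold it recovered 86% and 100% for the WT cytokine effect, 80% and 94% for the Adcy10-/- cytokine effect, and 88% and 98% for genotype at baseline. It recovered 94% and 100% for genotype with cytokines, 96% and 98% for the average, and 60% and 90% for the interaction. False calls were 3.5% to 6% of calls. The changed genes were drawn from the better expressed ones, and noise was independent between libraries, without the likeness of libraries of the same number. Genes changed by up to 8-fold in the same data also ease the threshold on adjusted p. Recovery therefore does not measure what the genotype tests could have missed in the real data.

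Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, a fit of only the groups compared, a replicate block, a block within genotype, array weights, no trend, a 2-fold limit, the highest entry per gene ID, and each library left out in turn. GRCm38 annotation served only for gene order, names and transcript lengths, and placed 99.6% of tested genes.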

Results

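Polyadenylated RNA was profiled in CD4+ T cells from wild-type (WT) and Adcy10-/- C57BL/6 mice cultured toward the Th17 lineage. Adcy10 encodes soluble adenylyl cyclase, an enzyme that makes the second messenger cAMP inside the cell. Cells of each genotype were kept for 18 hours in baseline medium or in that medium with polarizing cytokines, and each of the 4 groups held 3 libraries. The files give gene expression as FPKM, a value scaled for library size and transcript length. The 12 libraries each summed to between 547870 and 594750 FPKM and held between 9778 and 9925 genes at 1 FPKM or more. Read depth is unknown. Libraries of a group correlated with each other at 0.986 or more on the log scale. The labels do not say whether replicates came from separate animals, so the p-values below measure only the spread between these samples. The labels also do not list separately what baseline medium contained.

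The targeted gene was examined first. Adcy10 was listed at 0 FPKM in all 12 libraries, WT and Adcy10-/- alike, so it does not check the genotype labels. Of 10 genes that every cell uses, 0 were at 0 in any library. The first principal component held 34.3% of the variance and separated the media. The next component held 22.6% and separated replicate number 1 from numbers 2 and 3 in both genotypes.

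The response of WT cells to the polarizing cytokines was compared first, as the reference for the mutant. Il21, a cytokine made by Th17 and follicular helper cells, rose from 6.79 ± 5.78 to 69.5 ± 4.84 FPKM (SD, n = 3 per group), a log2 change of 3.43 (SE 0.50, adjusted p = 0.00314). Tigit, which encodes an inhibitory receptor, rose by 1.26 (SE 0.08, adjusted p = 2.36e-05). Eomes, a T-box factor of cytotoxic and Th1-type cells, showed the largest decrease, from 23.7 ± 4.35 to 2.39 ± 0.234 FPKM (log2 change -2.85, SE 0.16, adjusted p = 1.41e-05). The other leading increases were the metalloproteinase inhibitor Timp1 (log2 change 3.00), the transglutaminase Tgm2 (2.42), the interleukin-1 receptor antagonist Il1rn (2.07), the granzyme Gzma (1.94), Igfbp4 (1.83), Smim3 (1.68), the caspase Casp6 (1.65) and Frmd4b (1.57). The other leading decreases were Ms4a4c (log2 change -2.57), Dapl1 (-2.19), the interferon-inducible Mndal (-1.71) and Ifi203 (-1.51), Tnfsf11, which encodes RANKL (-1.66), Adh1 (-1.60), Ms4a4b (-1.51), the death ligand Fasl (-1.45) and the lymphotoxin gene Lta (-1.32).

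Signature Th17 cytokines other than Il21 did not pass in WT cells in the fit without a replicate block. Il17a stood at 24.7 ± 19.1 FPKM at baseline and 43.5 ± 19.3 FPKM with cytokines (SD, n = 3 per group; log2 change 0.93, SE 0.60, adjusted p = 0.45). Il17f gave 15.9 ± 16.1 and 67.4 ± 29.9 FPKM (log2 change 2.41, SE 0.83, adjusted p = 0.131), and Il22 gave 34.7 ± 24.2 and 91.1 ± 29.5 FPKM (log2 change 1.51, SE 0.60, adjusted p = 0.19). All 3 genes were higher with cytokines in 3 of 3 number pairs. The fit behind these p-values counts the spread between replicate numbers as error. Il10, which encodes an anti-inflammatory cytokine, rose (log2 change 1.10, SE 0.15, adjusted p = 0.0027), and Foxp3, the regulatory T cell factor, rose by 0.53 (SE 0.13, adjusted p = 0.0472). Csf2, Il2, Ifng, Tbx21, Gata3 and Crem did not pass, with log2 changes of -0.27, 0.87, -0.81, 0.01, 0.00 and 0.28. Rora and Il23r lay below the expression filter, at 0.389 to 1.03 and 0.29 to 1.01 FPKM over the 12 libraries.

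Among gene lists fixed in advance, Th17 transcription factors and receptors moved up: 6 of 20 tested members rose and 0 fell, or 9 and 0 adjusted over the list alone, with Maf (log2 change 1.18), Fosl2 (0.99) and Batf (0.97) among them (camera adjusted p = 2.38e-05). Targets of JAK-STAT3 signaling, the pathway downstream of IL-6 and IL-21, moved up with 7 of 18 higher and 1 lower, or 11 and 1 adjusted over the list alone. They included the feedback inhibitor Socs3 (log2 change 1.08; camera adjusted p = 1.48e-06). Regulatory T cell genes moved up with 5 of 15 higher and 0 lower, or 6 and 0 adjusted over the list alone, led by Tigit and the inhibitory receptor gene Ctla4 (0.63; camera adjusted p = 0.000128). In the Th2 list, 3 of 11 rose and 0 fell, or 3 and 1 adjusted over the list alone: Ecm1 (1.22), Il10 and the IL-4 receptor gene Il4ra (0.87; camera adjusted p = 0.0302, or 0.205 without WT cytokines replicate 1). With an estimated correlation, the adjusted p was 0.538 for the Th17 factors, the JAK-STAT3 targets and the regulatory T cell genes, and 0.549 for Th2 genes. In the Th17 cytokine list 2 of 14 rose (Il21, Il10) and 1 fell (Lta), or 3 and 2 adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.138), although it passed as higher without WT baseline replicate 3 (0.0265) or WT cytokines replicate 2 (0.0384).

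Metabolic genes moved with the cytokines as well. Among glycolytic genes 3 of 23 rose and 0 fell, or 11 and 2 adjusted over the list alone: the lactate exporter Slc16a3 (log2 change 0.77), the pyruvate kinase Pkm (0.50) and the hexokinase Hk1 (0.38; camera adjusted p = 2.38e-05). Hypoxia-response genes moved up with 3 of 18 higher and 0 lower, or 9 and 0 adjusted over the list alone: Egln3 (1.33), Ddit4 (0.46) and Ndrg1 (0.37; camera adjusted p = 2.43e-05). Ribosomal protein genes shifted up as a list although 0 of 51 passed singly, with 50 of 51 above 0 and a median log2 change of 0.09 (camera adjusted p = 1.85e-05). Genes of the mitochondrial respiratory chain shifted up by a median of 0.06 with 0 of 42 passing (camera adjusted p = 0.000702, or 0.24 without WT cytokines replicate 2). For both of these lists the count adjusted over the list alone was also 0, and quantile normalization ended the call (adjusted p = 0.343 and 0.132), while median-ratio scaling kept it (0.00013 and 0.000793). With an estimated correlation, the adjusted p was 0.549 for glycolysis, 0.538 for hypoxia and 0.854 for the ribosomal and respiratory chain lists.

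Interferon-stimulated genes moved down: 9 of 33 fell and 1 rose, or 10 and 1 adjusted over the list alone, including the GTPase genes Iigp1 (log2 change -0.94), Gbp4 (-0.88) and Irgm1 (-0.84) and the antiviral gene Ifit1 (-0.88; camera adjusted p = 0.000483). Its adjusted p was 0.538 with an estimated correlation. Members of the Th1 list fell in 4 cases (Eomes, Fasl, Xcl1, Stat4) and rose in 1, the chemokine receptor gene Cxcr3 (0.72), of 15 tested, with the same counts adjusted over the list alone. The list median was 0.06 and the mean -0.27, so they differ in sign, and the list did not pass (camera adjusted p = 0.384). In the NF-kB and IL-1 list 3 of 26 rose (Il1rn, Bcl3, Il1r1) and 2 fell (Lta, Bcl2a1b), or 4 and 7 adjusted over the list alone. Among cAMP-CREB response genes 2 of 29 rose (Nfil3 by 1.24, Fosl2) and 6 fell, among them the immediate early genes Nr4a3 (-1.12) and Fosb (-0.82), or 7 and 9 adjusted over the list alone. Neither list passed (camera adjusted p = 0.627 and 0.984).

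The other lists did not pass as lists in WT cells with all 12 libraries and no block, although single members did. T cell activation genes rose in 3 of 23 cases (Ctla4, Lag3, Cd5) and fell in 5, among them the early growth response gene Egr3 (log2 change -0.72) and the CD40 ligand gene Cd40lg (-0.48), or 6 and 6 adjusted over the list alone (camera adjusted p = 0.833; median 0.04, mean -0.01). Genes of naive and quiescent cells rose in 2 of 21 (Igfbp4, Satb1) and fell in 2 (Dapl1, Foxp1), and chemokine receptor and migration genes rose in 2 of 19, among them Cxcr3, and fell in 2 (Itga4, Itgal; camera adjusted p = 0.622 and 0.376). Apoptosis regulators fell in 3 of 20, among them Fasl and Bcl2a1b (0.622), and components of the cAMP pathway in 2 of 34, the prostaglandin E2 receptor gene Ptger4 (-0.42) and the transcription factor gene Creb1 (-0.30; 0.307). The integrated stress list held 2 increases of 19 (Ddit3, Ddit4; 0.202) and the unfolded protein list 2 of 19 (Xbp1, Pdia6; 0.153), while cell cycle (0 of 37; 0.401) and cholesterol synthesis genes (0 of 23; 0.622) held none. CD4 T cell identity genes rose in 3 of 18 (Cd5, Cd6, Cd2) and fell in 1 (0.307). Among markers of other cells, Gzma rose in the NK list (1 of 6; 0.138), Maf in the gamma delta list (1 of 5; 0.135) and Ctss fell in the macrophage list (1 of 7; 0.622). The CD8 T cell (0 of 6; 0.622), B cell (0 of 16; 0.732), dendritic cell (0 of 7; 0.457), neutrophil (0 of 5; 0.459) and red cell lists (0 of 6; 0.822) held none. With replicate number as a block within genotype, the Th17 cytokine (0.026), NK (0.0404) and gamma delta lists (0.00801) passed as higher and the dendritic cell list (0.0404) as lower.

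Over all genes, limma called 268 increases and 231 decreases in WT cells (499 of 10126; adjusted p under 0.05), of which 46 and 25 were at least 2-fold. All 499 had the same direction in each of the 3 number pairs, against 50.1% of all tested genes. The 499 were picked from these same libraries, so this adds no support. The 2 groups did not overlap for 20.8% of genes, against 10% by chance. With replicate number as a block, 1502 genes passed (750 up, 752 down), and all 499 were among them. Leaving out WT baseline replicate 2 left 164 calls, WT cytokines replicate 1 left 257 and WT cytokines replicate 2 left 324. Of the 68 named genes that passed, 28 passed without each of the 12 libraries in turn, among them Il21, Eomes, Maf, Il10 and Tigit, while Timp1, Tgm2, Il1rn and Gzma did not pass without WT baseline replicate 2 (adjusted p = 0.0625, 0.0635, 0.0625 and 0.0533). Foxp3 did not pass in 10 of those 12 fits and Batf in 9.

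The same comparison in Adcy10-/- cells asked whether the cytokine response was present without soluble adenylyl cyclase. Il21 rose from 5.98 ± 4.07 to 69.0 ± 5.82 FPKM (SD, n = 3 per group; log2 change 3.53, SE 0.50, adjusted p = 0.00235). Tigit rose by 1.10 (SE 0.08, adjusted p = 5.54e-05), and Eomes fell from 25.7 ± 5.06 to 2.50 ± 0.498 FPKM (log2 change -2.92, SE 0.16, adjusted p = 1.07e-05). Timp1 (log2 change 2.76), Tgm2 (2.28), Il1rn (2.07), Gzma (1.90), Igfbp4 (1.82) and Casp6 (1.57) again led the increases, with the NF-kB signaling scaffold Malt1 (1.64). Decreases were led by Ms4a4c (-2.52), Dapl1 (-2.15), Tnfsf11 (-1.55), Lad1 (-1.54), Mndal (-1.54), Fasl (-1.54), Adh1 (-1.52), Ms4a4b (-1.40) and Ifi203 (-1.38).

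Il17a, Il17f and Il22 did not pass in Adcy10-/- cells either, again in the fit without a replicate block. Their log2 changes were 0.65 (SE 0.60, adjusted p = 0.726), 2.26 (SE 0.83, adjusted p = 0.188) and 0.85 (SE 0.60, adjusted p = 0.598). Il17a was higher with cytokines in 3 of 3 number pairs, and Il22 in 2 of 3. Il10 rose by 1.02 (SE 0.15, adjusted p = 0.00396), and Foxp3 gave 0.38 (SE 0.13, adjusted p = 0.171). Csf2, Il2, Ifng, Tbx21, Gata3 and Crem gave -0.26, 0.95, -0.89, -0.16, -0.12 and 0.29 and did not pass.

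The lists that moved in Adcy10-/- cells were 6, each also called in WT cells. JAK-STAT3 targets rose in 6 of 18 cases and fell in 1, the kinase gene Pim2 (log2 change -1.04), or 11 and 1 adjusted over the list alone (camera adjusted p = 3.69e-08). Th17 factors and receptors rose in 5 of 20 and fell in 0, or 9 and 0 adjusted over the list alone, with Maf at 1.29 and the IL-21 receptor gene Il21r at 0.80 (camera adjusted p = 9.14e-07). Hypoxia genes rose in 2 of 18 (Bnip3 by 0.74, Ddit4), or 6 adjusted over the list alone (camera adjusted p = 4.99e-06). Interferon-stimulated genes fell in 9 of 33, or 12 with 1 rise adjusted over the list alone, including Ifit1 (-1.08) and the GTPase gene Tgtp1 (-0.81; camera adjusted p = 8.18e-05). With an estimated correlation, the adjusted p of these 4 lists was 0.407. Glycolytic genes rose in 3 of 23 (Slc16a3, Pkm, Eno2), or 6 with 1 fall adjusted over the list alone (camera adjusted p = 0.00012; adjusted p = 0.679 with an estimated correlation). Regulatory T cell genes rose in 3 of 15 (Tigit, Il10, Ctla4), or 7 with 2 falls adjusted over the list alone (camera adjusted p = 0.000195; adjusted p = 0.567 with an estimated correlation). The Th1 list held 5 decreases, among them Stat4 (-0.73), and 1 increase of 15 tested, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0554).

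With the replicate block the NF-kB and IL-1 list and the dendritic cell marker list also passed as lower in Adcy10-/- cells (camera adjusted p = 0.0178 for both), against 0.125 and 0.303 without it. With the block within genotype both were again lower (0.0348 and 0.00734), as was the B cell list (0.0117), and the Th2 (0.0301) and NK lists (0.0209) were higher, against 0.706, 0.0614 and 0.0829 without a block.

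Over all genes, limma called 217 increases and 215 decreases in Adcy10-/- cells (432 of 10126), of which 45 and 26 were at least 2-fold. All 432 kept 1 direction in the 3 number pairs, against 49.3% of all tested genes, and were likewise picked from these libraries. The groups did not overlap for 21.6% of genes (10% by chance). With the replicate block, 1086 genes passed (480 up, 606 down), all 432 among them. Leaving out KO cytokines replicate 1 left 196 calls, KO baseline replicate 1 left 198, KO baseline replicate 3 left 210, KO cytokines replicate 3 left 262 and KO cytokines replicate 2 left 283. Without the 4 libraries numbered 1, a check added after the data were seen, 205 passed. Of the 67 named genes that passed, 33 passed without each library in turn. Timp1 did not pass in 4 of these fits, Tgm2 in 3 and Il1rn in 1, with highest adjusted p = 0.0654, 0.0717 and 0.0504.

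The cytokine effects of both genotypes were compared gene by gene. In both, 174 genes rose and 157 fell, where independent lists of these sizes would share 5.74 and 4.90. All 600 genes called in either genotype changed in the same direction, with a correlation of 0.975 across these genes and a slope of 0.94 for Adcy10-/- on WT. Across all 10126 genes Pearson's r was 0.768 and Spearman's rho 0.714. Genes are not independent replicates, and no libraries are shared between these 2 comparisons.

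The difference between the cytokine effects was tested as an interaction of genotype and medium. Limma called 0 genes, with 112 at unadjusted p under 0.05 where 506 would be expected by chance. Il17a gave an interaction of -0.27 (SE 0.84), Il17f -0.15 (SE 1.17), Il22 -0.66 (SE 0.84) and Il21 0.10 (SE 0.70), each with adjusted p = 1.00. The smallest p-values belonged to Rpp25l (-0.34), 1700001O22Rik (-0.45), Anapc13 (-0.36), Rnu11 (6.45) and Hexim2 (0.41), all with adjusted p = 1.00; Rnu11, a small nuclear RNA, was listed at 0 in 8 of 12 libraries. Ribosomal protein genes were lower in the interaction as a list, with 51 of 51 members below 0 and a median of -0.08 (camera adjusted p = 4.3e-09), and so were respiratory chain genes with 34 of 42 below 0 and a median of -0.07 (camera adjusted p = 0.000121). Both gave adjusted p = 0.993 with an estimated correlation, and quantile normalization ended both calls (0.448 and 0.827), while median-ratio scaling kept both (4.16e-06 and 0.00155). The ribosomal call also ended without KO baseline replicate 1 (0.0791) or WT cytokines replicate 2 (0.0648), and the respiratory chain call without WT cytokines replicate 2 (0.432) or KO cytokines replicate 3 (0.159). In both lists 0 genes passed, also adjusted over the list alone. The Th17 cytokine list did not pass in the interaction (camera adjusted p = 0.808), but was lower without KO baseline replicate 1 (0.00258) and with array weights (0.0484). Without KO cytokines replicate 1, limma called Snora75, and without WT cytokines replicate 1 Mir703 (adjusted p = 0.000542 and 0.0118), both small RNAs named after their values were seen.

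The genotypes were then compared within each medium and averaged over media, the question being what loss of soluble adenylyl cyclase changed. No single gene passed with all 12 libraries at equal weight and no replicate block, and the intervals of the Th17 panel were wide. With cytokines, Il17a was 43.5 ± 19.3 FPKM in WT and 42.9 ± 17.7 FPKM in Adcy10-/- libraries (SD, n = 3 per group), a log2 difference of 0.02 with a 95% interval of -1.28 to 1.33. Il17f differed by -0.02 (-1.84 to 1.80), Il22 by 0.21 (-1.09 to 1.52) and Il21 by -0.01 (-1.10 to 1.08), each with adjusted p = 1.00. At baseline, Il17a differed by 0.30 (-1.01 to 1.61), Il22 by 0.87 (-0.43 to 2.18) and Foxp3 by 0.27 (-0.03 to 0.56). Crem, a cAMP-induced transcription factor gene, differed by 0.00 (SE 0.13) at baseline and 0.01 (SE 0.13) with cytokines.

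**Figure D1:**
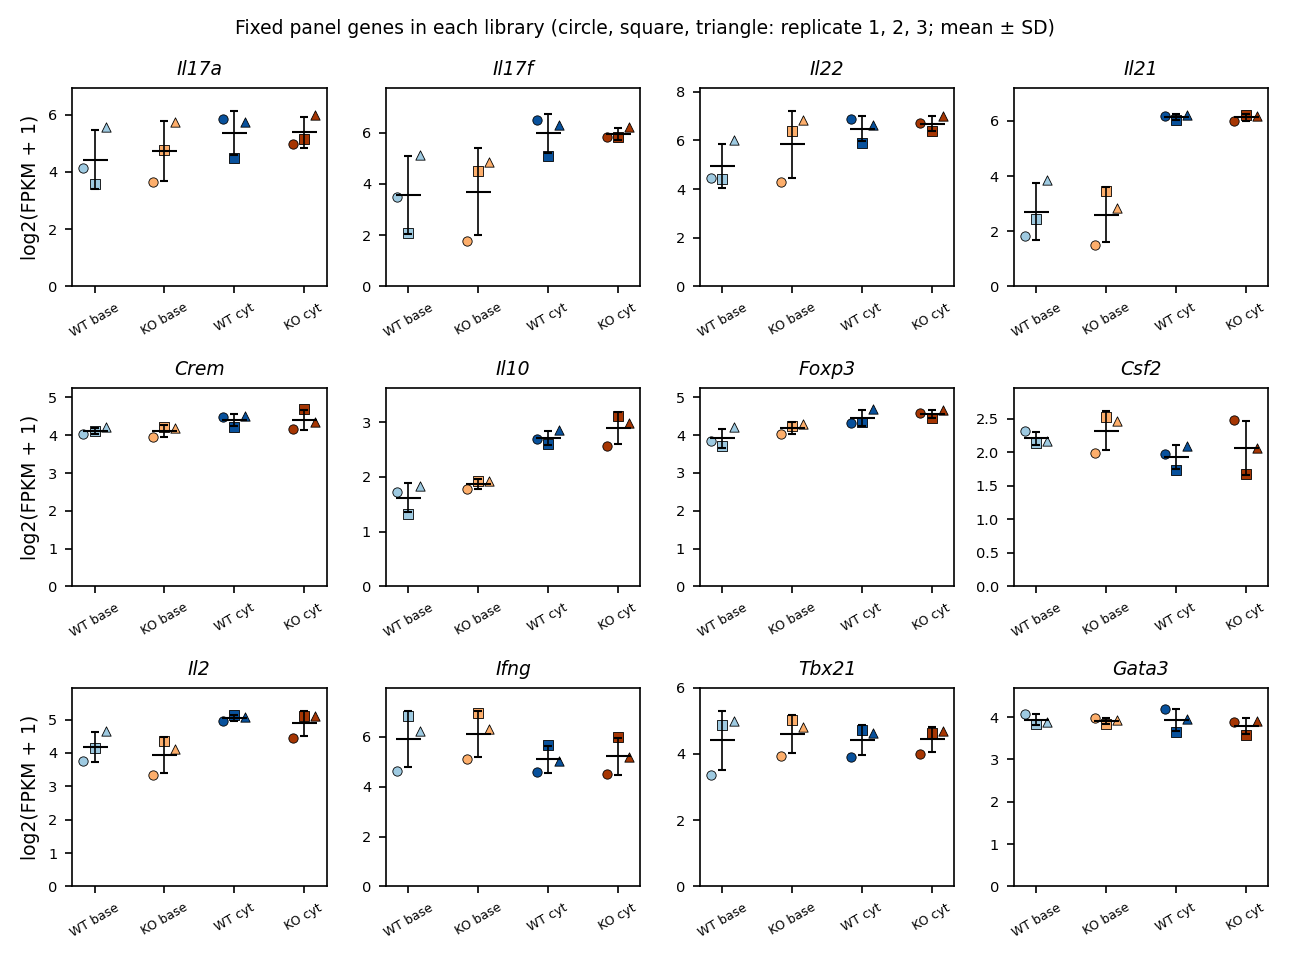
Expression of 12 fixed panel genes as log2(FPKM + 1) in each library, by genotype and medium; symbols give the replicate number, and bars the mean ± SD of 3 libraries. Il21 and Il10 separate by medium, and the genotypes overlap for Il17a, Il17f and Il22.

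Genes with the smallest p averaged over media included Mid1, a ubiquitin ligase gene, at -0.98 (SE 0.15, adjusted p = 0.133), the mitochondrial ribosomal gene Mrps14 at -0.33 (SE 0.05, adjusted p = 0.133), Spast, which encodes the microtubule-severing enzyme spastin, at -0.23 (SE 0.04, adjusted p = 0.268) and Ehd3 at -0.55 (SE 0.10, adjusted p = 0.461). Mid1, Mrps14, Spast and Ehd3 were lower in Adcy10-/- libraries in 6 of 6 number pairs. They were picked by p in these same libraries, so this direction was nearly given by the choice and adds no support. Over all genes, 3.8% had 1 direction in all 6 pairs, which rest on 3 replicate numbers. Leaving out KO baseline replicate 1 brought Mid1 past the threshold (adjusted p = 0.0202). Leaving out WT cytokines replicate 1 or KO cytokines replicate 1 did so for the small RNAs Mir703 and Snora75, averaged over media (adjusted p = 0.0218 and 5.76e-05) and with cytokines (0.000944 and 8.49e-06). At baseline the smallest p-values included those of Mid1, Spast, the stress-response factor gene Ddit3 (0.48, SE 0.12) and Mvb12a (0.20, SE 0.05). With cytokines they included those of Mrps14 (-0.41, SE 0.07), the urokinase receptor gene Plaur (-0.59, SE 0.12), Mid1 and Ehd3, and in both media each had adjusted p = 1.00.

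Genes next to Adcy10 on chromosome 1, by gene order in GRCm38, were lower in Adcy10-/- libraries as a list averaged over media, with 22 of 25 below 0 and a median of -0.05 (camera adjusted p = 9.6e-05). This was the sole list call held with an estimated correlation (adjusted p = 0.032). Of its members 0 passed over all genes, and 1 was lower adjusted over the list alone: Mpc2, a mitochondrial pyruvate carrier gene (-0.20, SE 0.04, lower in 6 of 6 number pairs). Mpc2 was picked by its p-value, so its number pairs add no support. The list was also lower at baseline (camera adjusted p = 0.00494; 0.0702 without WT baseline replicate 1 and 0.0727 without KO baseline replicate 2) and with cytokines (0.0046), where an estimated correlation gave adjusted p = 0.165 and 0.189.

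**Figure D2:**
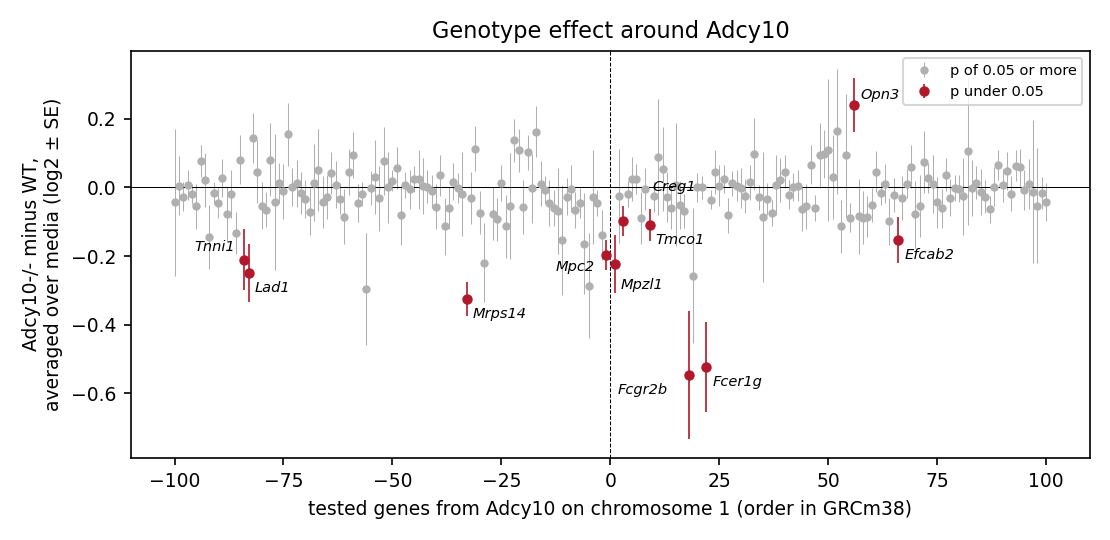
Difference between Adcy10-/- and WT averaged over media (log2, bars ± SE) for tested genes within 100 of Adcy10, in gene order of GRCm38; red points have unadjusted p under 0.05. Of the red points Opn3 is above 0 and the others below; the labeled genes were picked by these p-values.

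Markers of other immune cells differed between the genotypes. Markers of neutrophils, mast cells and basophils were lower in Adcy10-/- libraries averaged over media, with 5 of 5 below 0 and a median of -0.96, among them Il1b at -1.08 (SE 0.34) and the mast cell protease gene Cpa3 at -0.52 (SE 0.15; camera adjusted p = 2.31e-06, and adjusted p = 0.0838 with an estimated correlation). Macrophage and monocyte markers were lower with 6 of 7 below 0, including lysozyme, Lyz2, at -1.03 (SE 0.35; camera adjusted p = 0.000503, and adjusted p = 0.189 with an estimated correlation). The mean of the dendritic cell markers was lower in 6 of 6 number pairs, with the chemokine gene Ccl17 at -1.21 (SE 0.37). Its members Ccr7 (0.02, SE 0.10) and Batf3 (0.01, SE 0.27) were not lower. The list gave camera adjusted p = 0.00239, and adjusted p = 0.22 with an estimated correlation. NK and innate lymphoid markers were lower with 5 of 6 below 0, led by Fcer1g at -0.52 (SE 0.13), which myeloid cells also express. The list gave camera adjusted p = 0.00466, and adjusted p = 0.117 with an estimated correlation. Tyrobp gave -0.37 (SE 0.16). Klrd1, Klrc1, Gzma and Prf1 gave -0.08, 0.03, -0.13 and -0.19 (SE 0.16, 0.09, 0.25 and 0.15), so the call does not show a drop of NK cells. Tyrobp, Klrd1 and Prf1 are named outside the rule. No marker passed over all genes, while 2, 0, 1 and 1 members of these 4 lists, in this order, were lower adjusted over the list alone. Without the 4 libraries numbered 1 the macrophage list did not pass (0.0586).

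Within media, the neutrophil list was lower at baseline and with cytokines (camera adjusted p = 0.000937 and 0.000222; adjusted p = 0.235 and 0.272 with an estimated correlation). The macrophage list was lower at baseline (0.0301), where the call ended without WT baseline replicate 1 (0.377), WT baseline replicate 2 (0.0716) or KO baseline replicate 3 (0.491), and with cytokines (0.0046), where it ended without WT cytokines replicate 1 (0.279). The dendritic cell list passed with cytokines (0.011; 0.0996 without WT cytokines replicate 3 and 0.248 without KO cytokines replicate 1), and the NK list at baseline (0.0301; 0.0554, 0.115 and 0.149 without WT baseline replicate 1, WT baseline replicate 2 or KO baseline replicate 3). For the macrophage and dendritic cell lists with cytokines the adjusted p was 0.366 with an estimated correlation, and at baseline it was 0.638 for the macrophage and 0.235 for the NK list.

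B cell markers followed the replicate number more than the groups. Their mean log2(FPKM + 1) was 1.54 ± 0.208 in the 4 libraries numbered 1, 3.09 ± 0.388 in those numbered 2 and 3.07 ± 0.145 in those numbered 3 (SD, n = 4). The list did not differ by genotype averaged over media or with cytokines (camera adjusted p = 0.194 and 0.396), but with the replicate block it was lower in Adcy10-/- libraries with cytokines (0.00113), where it was lower in 2 of 3 number pairs and higher in number 1. Hemoglobin Hbb-b1, chosen after its values were seen, reached 73.6 and 44.4 FPKM in the Adcy10-/- libraries numbered 3 and lay between 0.156 and 9.52 FPKM in the other 10.

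**Figure D3:**
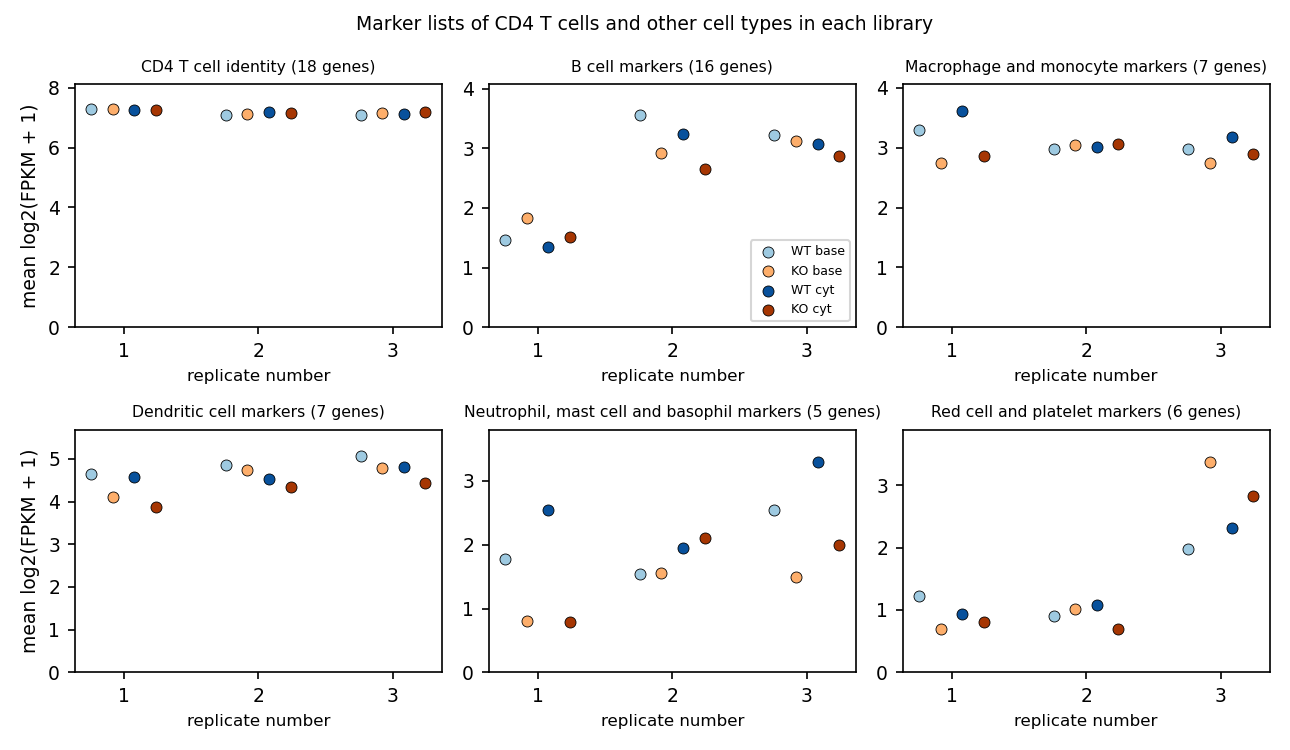
Mean log2(FPKM + 1) of 6 marker lists in each library, by replicate number and colored by genotype and medium. B cell markers are low in all 4 libraries numbered 1, and dendritic cell markers are lower in Adcy10-/- than in WT libraries within each number and medium.

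Other lists shifted slightly with genotype, beside these markers. Regulatory T cell genes were higher in Adcy10-/- libraries averaged over media (12 of 15 above 0, median 0.07; camera adjusted p = 0.000172), led by Tigit at 0.17 (SE 0.06), and at baseline (0.000937; 0.302 without WT baseline replicate 2). Interferon-stimulated genes were higher averaged over media (23 of 33 above 0, median 0.07; 0.000614), with Gbp4 at 0.21 (SE 0.08), and at baseline (0.00409). Omission of KO baseline replicate 2 or WT cytokines replicate 2 ended the averaged interferon call (0.0672 and 0.0993), and omission of WT baseline replicate 3 or KO baseline replicate 2 the baseline call (0.0805 and 0.603). Both lists gave adjusted p = 0.429 averaged over media and 0.638 at baseline with an estimated correlation.

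Hypoxia genes were lower averaged over media, with 18 of 18 below 0 and a median of -0.06 (camera adjusted p = 0.00281), and so were glycolytic genes with 21 of 23 below 0 (0.00239). Both calls ended without WT baseline replicate 3 (0.0899 for hypoxia, 0.515 for glycolysis) or WT cytokines replicate 3 (0.0648 and 0.0604), and the glycolysis call also without KO baseline replicate 1 (0.102). With an estimated correlation the adjusted p was 0.572 and 0.893. With cytokines, ribosomal protein genes were lower in Adcy10-/- libraries (50 of 51 below 0, median -0.06; camera adjusted p = 8.42e-08) and respiratory chain genes likewise (36 of 42 below 0, median -0.04; 2.63e-05). Both calls ended without WT cytokines replicate 2 (0.61 and 0.921) or KO cytokines replicate 3 (0.161 for each), and both gave adjusted p = 0.682 with an estimated correlation. Under quantile normalization both gave 0.461, and under median-ratio scaling 5.66e-05 and 0.000948. In each of these lists 0 members passed, and 0 adjusted over the list alone.

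With cytokines, glycolytic genes (camera adjusted p = 0.0046; 0.298 without WT cytokines replicate 3 and 0.161 without KO cytokines replicate 1), hypoxia genes and the NF-kB and IL-1 list (0.0493 each) were lower as well, all with adjusted p = 0.682 with an estimated correlation. The NF-kB and IL-1 call ended without KO baseline replicate 3, WT cytokines replicate 2, WT cytokines replicate 3 or KO cytokines replicate 1 (0.0533, 0.153, 0.229 and 0.99). The hypoxia call ended without those libraries except WT cytokines replicate 2 (0.0533, 0.64 and 0.172), and without WT cytokines replicate 1 or KO cytokines replicate 3 (0.0657 and 0.315). At baseline the hypoxia list was lower (0.0366) and the ribosomal and CD4 T cell identity lists higher (0.0301 each), with adjusted p = 0.903, 0.96 and 0.953 with an estimated correlation. The identity and ribosomal calls ended without WT baseline replicate 2 (0.584 for each) or WT baseline replicate 3 (0.792 for each). Without KO baseline replicate 1 the identity list had adjusted p = 0.991 and the ribosomal list was lower rather than higher (0.00681), and the hypoxia call ended without WT baseline replicates 1 or 3 or KO baseline replicates 1 or 3 (0.0889, 0.792, 0.372 and 0.132).

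Averaged over media, the ribosomal and respiratory chain lists passed as lower (0.0348 and 0.0278; adjusted p = 0.903 and 0.893 with an estimated correlation). Both calls ended without WT baseline replicate 1 (0.683 and 0.111), KO baseline replicate 2 (0.495 and 0.0509), KO baseline replicate 3 (0.996 and 0.174), WT cytokines replicate 2 (0.581 and 0.65) or KO cytokines replicate 3 (0.91 and 0.606). The ribosomal call also ended without WT cytokines replicate 1 (0.0633) and the respiratory chain call without WT baseline replicate 3 (0.118). Under median-ratio scaling they gave 0.214 and 0.15, and under quantile normalization 0.843, with the ribosomal list then above 0, and 0.51. The replicate block, with cytokines, also brought the regulatory T cell list (0.0389) and the cAMP pathway components (0.0339) past the threshold as higher, and the integrated stress and unfolded protein lists (0.00227 each) as lower; without the block they gave 0.0512, 0.0758, 0.0867 and 0.0583.

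The Th17 cytokine list did not pass between genotypes with all 12 libraries at equal weight (camera adjusted p = 0.132 at baseline, 0.57 with cytokines and 0.119 averaged). It passed as higher in Adcy10-/- libraries without KO baseline replicate 1 (2.02e-07 at baseline, 1.54e-05 averaged), WT baseline replicate 3 (0.00263 and 0.00372) or KO cytokines replicate 1 (0.0345 with cytokines, 0.00342 averaged). It was also higher with array weights (0.000903 at baseline, 0.00145 averaged) and without the 4 libraries numbered 1 (0.000355, 0.0232 and 9.09e-05 in the 3 comparisons). Genes of the cAMP-CREB response did not pass between genotypes with all 12 libraries (camera adjusted p = 0.134 at baseline, 0.969 with cytokines and 0.368 averaged). They passed as higher in Adcy10-/- libraries at baseline without KO baseline replicate 1 (0.00508) and averaged without WT cytokines replicate 1 (0.0338) or KO cytokines replicate 1 (0.0262). Without the 4 libraries numbered 1 they were higher in all 3 (0.000382, 0.00333 and 1.07e-05).

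Other settings ended some of these list calls as well. Averaged over media, the macrophage list did not pass with a mean of at least 5 FPKM (0.117), the NK list with no filter (0.16), the glycolysis list with array weights (0.183), the hypoxia list with array weights (0.0723) or no filter (0.0557), the ribosomal list with no filter (0.165) or no trend (0.0686) and the respiratory chain list with no trend (0.0602). At baseline, having no filter ended the calls of the interferon (0.0934), hypoxia (0.178), ribosomal (0.131), NK (0.495), macrophage (0.0519), CD4 identity (0.0578) and neighbor lists (0.0519). A mean of at least 5 FPKM ended those of the macrophage (0.292) and ribosomal lists (0.0514), quantile normalization those of the macrophage (0.0515), hypoxia (0.0515), ribosomal (0.331, against 0.0494 with median-ratio scaling) and CD4 identity lists (0.178), and array weights those of the neutrophil (0.0865), hypoxia (0.968) and ribosomal lists (0.345). A fit of only the groups compared ended the hypoxia call (0.0573). With cytokines, the macrophage call ended with a mean of at least 5 FPKM (0.318) and the glycolysis call with quantile normalization (0.0628). The NF-kB and IL-1 and hypoxia calls ended with a pseudocount of 0.1 (0.0553 each), no filter (0.0916 and 0.214), a mean of at least 5 FPKM (0.118 and 0.0751) or no trend (0.0568 and 0.055), and the former also with quantile normalization (0.0628) or array weights (0.0557). Without the 4 libraries numbered 1, the hypoxia (0.234), ribosomal (0.349) and macrophage calls (0.192) at baseline and the NF-kB and IL-1 (0.207), hypoxia (0.0753) and macrophage calls (0.163) with cytokines ended.

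Limma called 0 genes between the genotypes at baseline, with cytokines and averaged over media, with 118, 202 and 180 of 10126 genes at unadjusted p under 0.05 against 506 expected by chance. These fits leave out the replicate number, by which libraries resembled each other, so the shortfall does not show that fewer genes differ than by chance. With the number as a block, 0 genes passed at baseline and 0 with cytokines, where 515 had unadjusted p under 0.05. Averaged over media the block gave 560 such genes, and 3 passed: Mid1, Ehd3 and Mrps14 (limma adjusted p = 0.0111, 0.0163 and 0.0163). The count of 0 averaged over media thus depends on leaving the number out. Without the block the smallest adjusted p averaged over media was 0.133. Groups did not overlap for 5% of genes at baseline and 5.1% with cytokines, against 10% by chance. The median SE was 0.087 within a medium and 0.061 averaged, so 95% intervals spanned a median of ±0.191 and ±0.135 on the log2 scale. The averaged fit counts libraries of the same number and genotype as independent, though they correlated at 0.294 to 0.536. Its interval rests on that assumption. The genotype differences in the 2 media correlated with r = 0.232 and rho = 0.098 across genes.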

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

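The window tests without Fcer1g and Fcgr2b and without all cell type markers were chosen after the results were seen.

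Ribosomal protein and respiratory chain genes drew attention because their cytokine effects differed between the genotypes in a test of the interaction (camera adjusted p = 4.3e-09 and 0.000121, and adjusted p = 0.993 for both with an estimated correlation). A single library could account for the ribosomal shift (adjusted p = 0.0791 without KO baseline replicate 1). Scaling was left open: quantile normalization moved the median from -0.083 to -0.005 at a similar SD over members (0.035 and 0.031, adjusted p = 0.448). Median-ratio scaling kept the ribosomal (median -0.074, 4.16e-06) and respiratory chain calls (0.00155). Ribosomal genes were highly expressed, with a mean log2(FPKM + 1) of 10.8 to 11.0 per library against medians of 3.62 to 3.69 over tested genes. Quantile normalization gives the top of every library the same values, so it would also remove a real joint shift of these genes. Its result cannot tell that from a technical difference. Short transcripts could account for part: 1868 other genes with transcripts under 1000 nt had a median interaction of -0.033 against -0.004 for 7823 longer ones. That was at the 0.01 percentile of 10000 random sets matched on expression. The 5th percentile of these sets was -0.023, so part of the gap to the longer genes may come with expression level. Short genes can also vary together, which random sets do not copy, so the percentile can overstate how rare such a median is. Of the 93 list genes, 69 are that short. The list genes lay lower, at -0.08 for short and -0.05 for longer ones, which goes against length as the whole account, though the spread of these medians was not tested. A weaker rise of translation and respiration genes in Adcy10-/- cells, the biological explanation, was not separated from these.

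Myeloid markers (macrophage, neutrophil and dendritic cell lists) were lower in Adcy10-/- libraries, with a median of -0.37 and 16 of 19 below 0. A second list of myeloid genes, written before its values were seen, had 18 of 19 tested members below 0 and a median of -0.26, at the 0.01 percentile of 10000 random lists matched on expression, the smallest they can give. That fits fewer myeloid cells in those libraries. The negative selection of CD4+ T cells is meant to remove such cells, though, and how many were left was not measured. The random lists hold unrelated genes, whereas myeloid genes can vary together, so the percentile can overstate how rare such a median is. With an estimated correlation, the fixed macrophage, neutrophil and dendritic cell lists did not pass averaged over media. The second list reads the same libraries and is no independent test of genotype. The median of the fixed markers stayed below 0 without each library in turn (highest -0.252), so no single library sets its sign. Libraries of the same number and genotype resembled each other, so each omission kept a partner library. Leaving out both was not tested, and 1 source sample was not excluded as the cause. Macrophage and neutrophil lists were lower in the 4 pairs numbered 1 and 3 and not in those numbered 2, and lower expression per cell in Adcy10-/- mice may also fit and was not tested.

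Genes near Adcy10 were the sole list to pass between genotypes with an estimated correlation. Among the 197 tested genes within 100 of Adcy10, without 3 genes whose values had been seen, 9 had unadjusted p under 0.05 (8 lower, 1 higher in Adcy10-/- libraries), and 0.438% of 5931 other windows, which overlap each other, held as many. That fits a strain variant carried along with the targeted gene, but part of the excess rests on Fcer1g and Fcgr2b, which myeloid cells express. Without these genes 7 of 195 remained, and 7.9% of windows held as many. They were left out of this window alone, so the count had to fall. Their removal cannot tell whether a variant or fewer myeloid cells lowered them. With all cell type markers left out of every window, 5.07% of windows held as many. The camera call of the list held without each library in turn, with a highest adjusted p of 0.00158. Each omission kept the other library of that number and genotype, so 1 source sample was not excluded as the cause.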

How the results depend on the processing

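The omission of the 4 libraries numbered 1, and the averaging of both media per number (0 genes for genotype), were chosen after seeing the data. Pseudocount, filters, scalings, trend and entries per gene ID left the WT cytokine count between 361 and 501, the Adcy10-/- count between 320 and 434 and the genotype and interaction counts at 0. The WT count moved from 499 to 275 with only the groups compared, 1502 with the replicate block, 1574 with the block within genotype, 1233 with array weights and 71 at 2-fold, and spanned 164 to 536 without 1 library. The Adcy10-/- count moved from 432 to 1086, 1193, 689 and 71 under the last 4 of these settings and to 205 without number 1, spanning 196 to 465 without 1 library. Genes shared by both effects moved from 331 to 190, 858, 925, 557 and 61 under the same 5 settings and to 172 without number 1, spanning 155 to 352. For the 2-fold limit the cause is its construction, and omissions leave fewer samples; otherwise the cause was not tested. Between genotypes at baseline, array weights gave 1 gene (Mid1). With cytokines, 0 to 1 passed without 1 library and 2 without number 1 (Mir703, Snora75). Averaged, 3 passed with the replicate block (Mid1, Ehd3, Mrps14), 3 with array weights (among them Mid1 and Mrps14), 2 without number 1 (Mid1, Snora75) and 0 to 1 without 1 library; the interaction gave 1 without number 1 (Snora75) and 0 to 1 without 1 library. With the replicate block 375 genes at baseline, 560 averaged and 335 in the interaction had unadjusted p under 0.05. Mir703 and Snora75 were named after their values were seen. Of the 192 list tests 46 passed, 1 with an estimated correlation, 79 without number 1 and 43 to 67 without 1 library. With the block within genotype 4 list tests came past the threshold for WT, 5 for Adcy10-/- and 1 for the interaction (integrated stress, lower, 0.012). With the replicate block 15 list tests came past the threshold and 2 lost it, the NK and macrophage lists at baseline (adjusted p = 0.054 and 0.0655); the B cell list averaged over media went from 0.194 to 0.000195, and to 5.11e-22 without number 1, but was 0.253 with 1 value per number and genotype, where 11 lists passed, all of them also among the 46. Directions reversed for the cAMP-CREB list with cytokines without number 1 (higher, 0.00333) and the ribosomal list averaged under quantile normalization (0.843), and the cause was not tested. Without 1 library, lists that reversed at least once spanned these adjusted p: at baseline, cell cycle 0.000133 to 0.946, ribosomal 1.81e-06 to 0.792 and CD4 identity 1.1e-05 to 0.991; with cytokines, NF-kB and IL-1 0.00551 to 0.99 and cell cycle 0.000628 to 0.982; averaged, cell cycle 0.00399 to 0.929, respiratory chain 0.000108 to 0.65 and ribosomal 5.68e-09 to 0.996; in the interaction, cell cycle 0.00501 to 0.967 and B cell 0.014 to 0.884. For named genes, 0 directions reversed; the replicate block brought 15 of 363 values past the threshold and dropped 0. Tests that need counts were not run, since the files hold FPKM. A fit of only the groups compared has no value for the averaged and interaction contrasts or the count of lists, and the block within genotype only applies to the cytokine effects and the interaction. Depth is unknown, so its limit on low genes could not be given.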

Other observations

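The splits of the libraries for the genotype and interaction contrasts were chosen after the results were seen.

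The cytokine effects were compared with those of other splits of the same 6 libraries. For WT, 1 of 10 splits, the real one, called as many genes as the 499 called, and the highest other called 2. For Adcy10-/- it was again 1 of 10, with 432 called and 1 in the highest other. With 10 splits, a share under 0.05 cannot be reached. Between genotypes the real count was 0, which 10 of 10 splits reach by construction at baseline (highest other 7) and with cytokines (highest other 0), so these counts test nothing.

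For the genotype effect averaged over media and for the interaction, 100 of 100 splits likewise reach the real count of 0 by construction. The highest other called 689 genes in each, and both are 1 contrast of the libraries: the averaged split put WT number 2, WT number 3 and KO number 2 against WT number 1, KO number 1 and KO number 3 in both media, and the interaction split swapped its sides with cytokines. It points to a structure of the samples other than genotype, with both genotypes of number 1 on the same side. Each side of a split held 3 libraries per medium, so a side with both libraries of number 1 had to hold 1 more. KO number 3 beside them is therefore no sign of likeness. On the second principal component KO number 3 lay at -9.69 and -5.93, and number 1 at 12.73 to 15.5. B cell markers, low in number 1 alone, could match no such split fully, and what the replicate number stands for is not stated.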
